A study of Mus musculus with 6 samples.

How the data were processed

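Gene expression was measured with TempO-Seq, a targeted assay in which pairs of detector oligonucleotides that anneal side by side on an RNA are ligated, amplified and sequenced directly from cell lysate. Per the labels' protocols, islets of 3 male C57Bl/6 mice were cultured for 48 h with cisplatin at 10 uM or with its vehicle, saline at 0.9%, and libraries were made with a mouse whole transcriptome probe panel. Islets of each mouse were divided between both arms, which gave 3 cisplatin and 3 vehicle libraries.

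The deposited table holds counts, which the authors made as whole numbers per probe and library. It has 30146 probe rows for 21400 gene symbols, and no row was left without a gene name. The submitters' processing notes name fastp 0.23.2, STAR 2.7.10b and DESeq2 1.44.0, with no role or settings. The genome build or probe sequence set used for alignment and the counting rules are not given in the sources used here. Probe positions within transcripts were not used here, so a row reports the stretch of RNA that its probe covers and not the whole transcript. Whether probes of near-identical genes share reads cannot be told from the table.

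Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Rows were kept by edgeR's expression filter with a minimum count of 10, which left 9381 rows for 7193 genes. Libraries were scaled with TMM factors, and each row was tested with the quasi-likelihood F-test (robust fit, treatment as the only term). P-values were adjusted with the Benjamini-Hochberg method, and a row was called at an adjusted p under 0.05, two-sided. Standard errors (SE) of log2 fold changes were obtained from the fold change and its F statistic. Log2 fold changes are given as cisplatin minus vehicle with SE, and CPM values are TMM-scaled with the SD over 3 libraries. The p-values measure the spread between the 3 libraries of each arm, which holds animal and assay variation together. The reported fit does not use that both arms come from the same 3 mice.

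A total of 24 gene lists were fixed from general knowledge before the data were examined. A gene with several probes was represented in its list by the probe with the highest mean CPM. Lists with 5 or more tested members, 19 in all, were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera compares a list with the other tested rows. Counts of called members are given over all rows tested and, separately, adjusted over the list alone. Shares of library counts were compared with a two-sided exact permutation test, for which the smallest p with 3 against 3 libraries is 0.1. The shares are of all counts in a library, so rows that take more counts lower the shares of the rest.

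Genes were named by a rule set before the data were examined. It took the 8 largest rises and the 8 largest falls among called rows with a mean CPM of 10 or more and the same direction in all 3 mouse pairs. It also took up to 4 called members of each list with the largest change, or the 2 most abundant members where none was called. Named whatever their values were Cdkn1a, Mdm2, Trp53, Ins1, Ins2, Gcg, Sst, Pdx1, Mafa, Nkx6-1, Slc2a2, Ucn3, Abcc8, Kcnj11, Mki67, Gdf15 and Aldh1a3. Some genes that the rule named are not reported here, while counts over all rows and over lists include them. Where a row had 0 counts in a whole group, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. Floors and intervals cover counting error only, since amplified reads are not independent molecules.

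The pairing of libraries comes from the labels, which give both libraries of a mouse the same animal identifier. Deviations from the group means correlated across rows at -0.116, 0.0336 and 0.219 in the 3 mouse pairs. Between cisplatin and vehicle libraries of different mice they correlated at -0.227 to 0.168, so these values do not clearly set the mouse pairs apart. The fit without a mouse term is reported, since no source states that the authors' fit used one, and the fit with the mouse as a block was run as an alternative. Other alternatives were RLE factors, upper quartile factors, library totals alone, no filter, a filter at a mean CPM of 10, DESeq2 1.42.0, limma-voom, probes summed per gene, thinning to the shallowest library, the 10 most abundant rows left out, and each library or mouse left out. No pair of libraries agreed within sampling noise.

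The analysis was tested on simulated counts for the cisplatin against vehicle comparison, drawn for 9381 rows with the real means, library sizes and dispersions. Of 89 tested rows changed 2-fold, 7 were called, and of 91 tested rows changed 4-fold, 57 were called, all in the right direction. Among 8325 unchanged rows 6 were called. A simulated list of 25 rows raised 2-fold was called, and 0 of 18 unchanged lists were. Rows were drawn independently of each other, so the simulation does not show how correlation between genes affects the list calls.

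Gene positions and genomic spans come from GENCODE M21 on GRCm38, matched by symbol for 98.5% of the panel's genes. This annotation need not be the one the authors used. Figures and rank tests were made with Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.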

Results

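Cisplatin is a platinum compound that crosslinks DNA and is used in chemotherapy. The series asked how it alters gene expression in isolated mouse islets, the endocrine clusters of the pancreas that hold insulin-producing beta cells and glucagon-producing alpha cells. The cisplatin libraries held 1116916, 1348297 and 1366829 counts, and the vehicle libraries of the same mice held 1998063, 1470227 and 2272276. The mean total was 1277300 ± 139200 (SD, n = 3) with cisplatin and 1913500 ± 407700 (SD, n = 3) with vehicle, an exact permutation p of 0.1, the smallest possible. Between 7175 and 8305 probe rows reached 10 counts in cisplatin libraries, against 9783 to 11216 in vehicle libraries.

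Islets exposed to cisplatin differed from vehicle islets of the same mice in 2344 of 9381 tested rows. The p53 target Cdkn1a, an inhibitor of the cell cycle, rose 21.9-fold, while Mafa, a transcription factor of mature beta cells, fell 7.49-fold and Pcsk2, a convertase that processes proinsulin and proglucagon, fell 10.9-fold. The most abundant probes of Ins1 and Ins2, the mouse insulin genes, did not pass the test, while a less abundant Ins2 probe was called higher. Of the called rows 1040 were higher and 1304 lower, and 2232 changed at least 2-fold. With library totals alone as the scale, the split was 459 higher and 2023 lower, since that scale moved the median of all rows from -0.07 to -0.54. Without vehicle library 1 the count was 1085 and without vehicle library 3 it was 1321. Pearson correlations of log2 CPM were 0.804 to 0.858 among cisplatin libraries, 0.884 to 0.959 among vehicle libraries and 0.624 to 0.738 between groups.

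**Figure D1:**
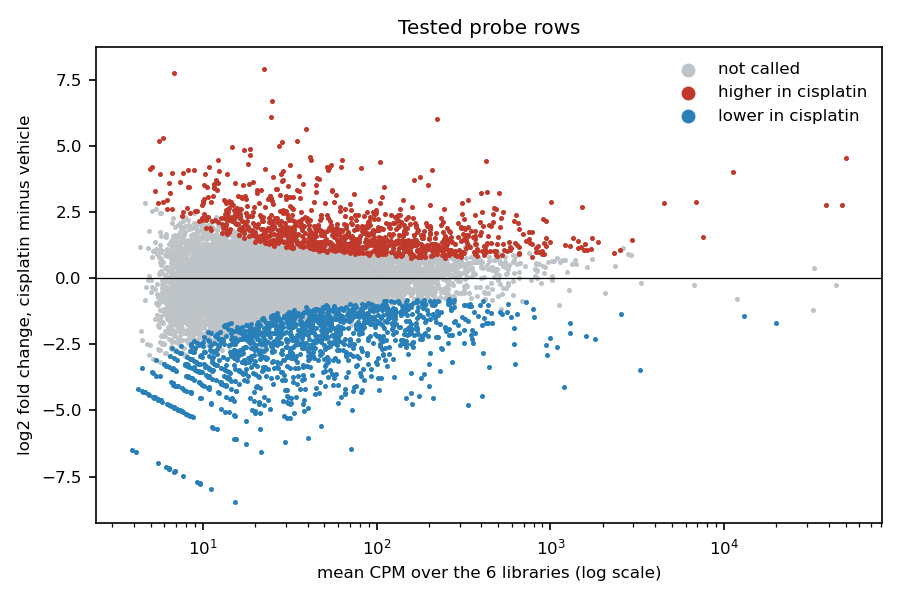
Log2 fold change of each tested probe row, cisplatin minus vehicle, against its mean CPM over the 6 libraries on a log axis. Red points are the 1040 rows called higher, blue points the 1304 called lower and grey points rows not called.

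The p53 target genes rose as a group. Of 23 tested members 16 were called higher and 1 lower, the same numbers adjusted over the list alone, with a median log2 fold change of 2.09 (camera, adjusted p = 2.0e-08). The call held with an estimated correlation (adjusted p = 0.0479) but not with an estimated correlation and a mouse block (adjusted p = 0.254). Without cisplatin library 3 or with library totals alone 2 members were lower. Phlda3, a repressor of Akt signalling, went from 7.73 ± 4.56 to 524 ± 153 CPM (log2 fold change 6.04 ± 0.44, adjusted p = 8.5e-06). Cdkn1a (chromosome 17, 29090976 to 29100727) went from 43.7 ± 15.9 to 951 ± 52.9 CPM, a log2 fold change of 4.45 ± 0.34. Phlda3 was at 6.63 without vehicle library 3. Psrc1 rose by 6.11 ± 0.65, and Tnfrsf10b, a death receptor, rose by 5.14 ± 0.64. The most abundant Mdm2 probe had 16 counts in all cisplatin libraries and 17 in all vehicle libraries and that of Trp53 had 15 and 23, too few to be tested. Gdf15 was not called (0.69 ± 0.65), and its value was -0.45 without cisplatin library 1. The tested p53 list members had a median genomic span of 7.03 kb.

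Among DNA repair genes 1 of 18 tested members rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.570). Ube2t, a ubiquitin-conjugating enzyme of crosslink repair, rose by 2.27 ± 0.52. Atm, a kinase that signals DNA breaks, changed by -1.09 ± 0.37 and Atr by -3.23 ± 0.93. With a mouse block 1 member fell, and Atr was no longer called (adjusted p = 0.0542). The number that fell was 0 without vehicle library 1 or 2, 1 without vehicle library 3 and 5 with library totals alone, and 2 members rose without cisplatin library 1 or 2 or vehicle library 3. Atm was not called without any single library other than cisplatin library 2 (adjusted p = 0.0775 to 0.154). Atr was not called without cisplatin library 2 (adjusted p = 0.0602) or vehicle library 1 (adjusted p = 0.0844) or 2 (-2.51, adjusted p = 0.149), and was at -4.03 without cisplatin library 3, while Ube2t was at 2.97 without vehicle library 2. Of 16 apoptosis regulators 1 rose, also adjusted over the list alone, namely Bcl2l11, which codes for the death activator Bim (1.45 ± 0.39; camera adjusted p = 0.0705). The number that rose was 0 without vehicle library 3 or with library totals alone, 2 without cisplatin library 1 or after thinning and 3 without cisplatin library 3. Bcl2l11 itself was not called without cisplatin library 2 (adjusted p = 0.0611) or vehicle library 2 (adjusted p = 0.0521) or 3 (adjusted p = 0.0933). Of the 32 cell cycle genes 4 were tested and 2 rose, with 3 adjusted over the list alone, in islets where Mki67 had 8 counts with cisplatin and 6 with vehicle. These were Mcm2 (1.48 ± 0.38) and Pcna (1.12 ± 0.38), and Pcna was not called with a mouse block (adjusted p = 0.0538) or without any single library other than cisplatin library 3 (adjusted p = 0.0520 to 0.122). Without vehicle library 1 or 3, or with library totals alone, 0 cell cycle genes rose, and 1 rose after thinning or without cisplatin library 2 or vehicle library 2. Of 5 senescence and secretory phenotype genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0575). The chemokine Cxcl1 had 170 counts with cisplatin and 1 with vehicle, a ratio of 357 (95% counting interval 63.2 to 14190). Ccl7 had 42 and 2 counts, a ratio of 44.1 (11.5 to 376), and the vehicle counts of both lay in vehicle library 3. Timp1 rose by 3.52 ± 0.41, and the angiogenic factor Vegfa changed by -1.25 ± 0.32, with 0 senescence genes lower without vehicle library 1 or 3 and Vegfa not called without cisplatin library 1 (adjusted p = 0.0583).

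Beta cell identity and maturity genes fell as a group. Of 29 tested members 15 were called lower and 0 higher, against 18 lower and 1 higher adjusted over the list alone, with a median log2 fold change of -1.36 (camera, adjusted p = 3.2e-05). The adjusted p was 0.0517 with an estimated correlation, and 1 member was higher without cisplatin library 1. Trpm5, a calcium-activated cation channel, went from 1999 ± 814 to 115 ± 40.4 CPM (-4.12 ± 0.40, adjusted p = 3.5e-05). Pcsk2 (chromosome 2, 143546156 to 143816285) changed by -3.45 ± 0.32, Mafa (chromosome 15, 75745490 to 75748228) by -2.90 ± 0.32 and Ucn3, a marker of mature beta cells, by -2.73 ± 0.43. Nkx6-1, a beta cell transcription factor, changed by -1.93 ± 0.29. The glucose transporter gene Slc2a2 was not called (-1.80 ± 0.75, adjusted p = 0.0957), though it was called lower with library totals alone. Pdx1 had 6 counts with cisplatin and 34 with vehicle and was not tested. The most abundant Ins1 probe had a log2 fold change of -0.26 ± 0.50, which was 0.08 without cisplatin library 3, and the most abundant Ins2 probe had 0.39 ± 0.49. A less abundant Ins2 probe was called higher (1.55 ± 0.46, adjusted p = 0.0251). Its CPM values were 19488, 8071 and 7464 with cisplatin and 2518, 5771 and 3653 with vehicle, highest in cisplatin library 1. Its call was not checked without single libraries. Insulin probes took 7.70% ± 3.80 of cisplatin counts and 9.23% ± 1.49 of vehicle counts (SD, n = 3, exact permutation p = 0.7). The cisplatin libraries held 9.7%, 10.1% and 3.31%, so the lower cisplatin mean rests on library 3. These are shares of all counts, and mitochondrially encoded rows alone took 28.6% of that library. On the TMM scale the most abundant probes were also lowest in cisplatin library 3. Ins1 had 20976 CPM there against 35722 and 63787 in cisplatin libraries 1 and 2, and Ins2 had 20099 against 36343 and 57471. The listed genes had a median genomic span of 16.8 kb, and lists matched on span and abundance had a median of 0.23.

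**Figure D2:**
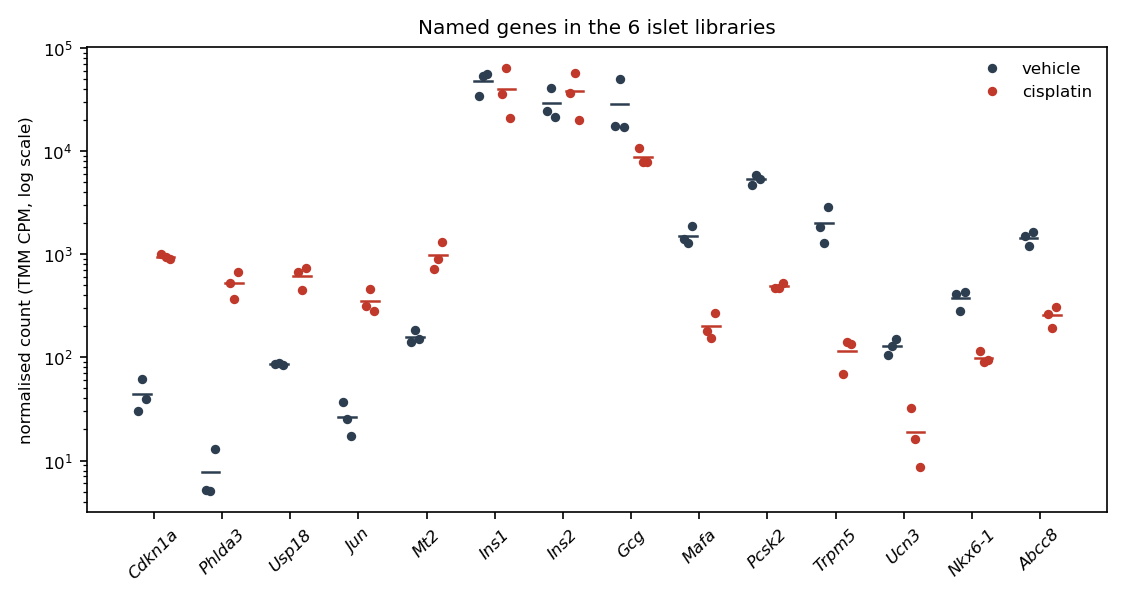
Normalised counts (TMM-scaled CPM, log axis) of 14 named genes, with 1 point per library, 3 per group, and a bar at each group's mean. Cdkn1a lies at 951 ± 52.9 CPM with cisplatin and 43.7 ± 15.9 with vehicle, while the groups overlap for the most abundant probes of Ins1 and Ins2.

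Genes of stimulus-secretion coupling and exocytosis also fell. Of 29 tested members 17 were called lower and 2 higher, the same adjusted over the list alone, with a median of -1.40 (camera, adjusted p = 2.9e-04, or adjusted p = 0.120 with an estimated correlation). The number lower was 11 without vehicle library 1, and 1 was higher with library totals alone. Cadps, a priming factor of dense-core vesicles, changed by -4.19 ± 0.58, Ptprn2, a secretory granule membrane protein, by -4.18 ± 0.53 and Pclo, a protein of the active zone, by -4.07 ± 0.41. Cadps was at -4.91 without cisplatin library 2, and without cisplatin library 3 Ptprn2 was at -4.80 and Pclo at -4.68. The most abundant probe of the calcium channel subunit gene Cacnb2 had 2 counts with cisplatin and 86 with vehicle, a ratio of 20.5 (95% counting interval 5.50 to 172), and was not called without vehicle library 1 (adjusted p = 0.145) or 3 (adjusted p = 0.0600). Of the ATP-sensitive potassium channel genes, Abcc8 fell from 1452 ± 229 to 255 ± 57.5 CPM (-2.51 ± 0.30), and Kcnj11 was not called (-1.55 ± 0.75, adjusted p = 0.147), though it was called lower with library totals alone, with no filter and without cisplatin library 2 or mouse 2. The members had a median genomic span of 47.3 kb, and Pclo, Cacnb2, Cadps and Ptprn2 spanned 349, 385, 451 and 791 kb.

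Markers of other cell types moved unevenly. Of 6 alpha cell markers 3 fell, also adjusted over the list alone (median -1.02, camera adjusted p = 0.0705). Gcg, the glucagon gene, changed by -1.70 ± 0.49 and took 0.757% ± 0.324 of cisplatin counts against 3.20% ± 1.94 of vehicle counts (SD, n = 3, exact permutation p = 0.1, the smallest possible). The vehicle libraries held 2.24%, 5.44% and 1.92%, and without vehicle library 2 the log2 fold change of Gcg was -1.01 and not called (adjusted p = 0.0914). Gcg was also not called without cisplatin library 2 (adjusted p = 0.0627) or 3 (adjusted p = 0.0632). Slc7a2 changed by -2.25 ± 0.31, and the most abundant Irx1 probe had 0 counts with cisplatin and 100 with vehicle, 48 of them in vehicle library 2, at least 15.9-fold lower. Of 5 delta and PP cell markers 1 fell, or 3 adjusted over the list alone, with Pyy at -1.28 ± 0.36 and Sst, the somatostatin gene, not called at -0.57 ± 0.38 (camera adjusted p = 0.255). With a mouse block 3 of these fell, as did 3 without cisplatin library 1 or vehicle library 3 or with library totals alone and 2 after thinning, while 0 fell without cisplatin library 2 or 3 or vehicle library 2. Sst took 0.141% ± 0.0905 and 0.270% ± 0.111 of counts (SD, n = 3, exact permutation p = 0.2). The Gcg and Sst shares are of all counts, including mitochondrial and repeat-like rows, which took more of the cisplatin libraries. Immune cell markers fell, 5 of 9 and 6 adjusted over the list alone, with a median of -1.89 (camera adjusted p = 0.00113, or adjusted p = 0.152 with an estimated correlation). Examples were Cd74 (-4.80 ± 0.94), H2-Aa (-3.77 ± 0.71) and C1qa (-3.03 ± 0.60), and the most abundant Csf1r probe had 1 count with cisplatin and 70 with vehicle, a ratio of 33.3 (5.79 to 1335). Without vehicle library 1 or 3 the number that fell was 3. Cd74 was at -4.10 without cisplatin library 1, and its 4 cisplatin counts lay in cisplatin library 2. H2-Aa was at -3.05 without cisplatin library 1 and -4.42 without cisplatin library 3, and the Csf1r probe, with its cisplatin count in library 3, was not called without any single vehicle library (adjusted p = 0.0514 to 0.0893).

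Of 6 stromal markers 1 fell, also adjusted over the list alone, the pericyte gene Rgs5 (-4.74 ± 0.74, or -6.06 without cisplatin library 2; camera adjusted p = 0.661), and 1 rose without cisplatin library 3, without vehicle library 3 or without mitochondrial and repeat-like rows. Of 3 tested endothelial markers Kdr (-3.35 ± 0.65) and Eng (-2.54 ± 0.71) fell and Esam rose (1.19 ± 0.40), also adjusted over the list alone, and Esam was not called with a mouse block (adjusted p = 0.0676), with library totals alone, after thinning or without any single library other than cisplatin library 1. Eng was not called without vehicle library 1 (adjusted p = 0.153) or 3 (adjusted p = 0.0910), where 1 endothelial marker fell, and Kdr was at -4.39 without cisplatin library 1. None of 4 tested duct markers was called over all rows or adjusted over the list alone, with Krt7 at 0.22 ± 0.32, below 0 with library totals alone. With a mouse block 1 was called higher, Spp1 (1.00, adjusted p = 0.0462, against 0.93 and adjusted p = 0.0593 without the block), picked after its values were seen, and it was also called without vehicle library 2 (1.32), after thinning and with DESeq2 or limma-voom. Acinar markers took 0.00335% of cisplatin counts and 0.00213% of vehicle counts (exact permutation p = 0.5), and the tested member, Bhlha15, was not called (0.88 ± 0.84). Cela1 had 17 and 20 counts and was not tested. The tested genes that beta cells normally repress were Zyx (1.03 ± 0.70) and Lmo4 (0.38 ± 0.54, below 0 with library totals alone), neither called over all rows or adjusted over the list alone, while Fcgrt, not tested in the reported fit and picked after its values were seen, was called higher without cisplatin library 2. The most abundant Aldh1a3 probe had 1 count with cisplatin and 0 with vehicle, and the other probe 0 and 1.

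Interferon response genes rose, 8 of 10 and the same adjusted over the list alone, with a median of 2.53 (camera adjusted p = 2.8e-05, or adjusted p = 0.0517 with an estimated correlation). The number that rose was 5 without vehicle library 1 or 3, where Isg15 was not called (adjusted p = 0.0734 and 0.0634). Ifit1 rose by 4.31 ± 0.76, Rsad2 by 3.94 ± 0.50, Isg15 by 3.62 ± 0.86 and Usp18, an interferon-induced protease, by 2.84 ± 0.29, with Ifit1 at 5.55 without vehicle library 2 and Rsad2 at 4.53 without vehicle library 1. Immediate early genes rose, 6 of 8 and 7 adjusted over the list alone, with a median of 2.0 (camera adjusted p = 3.2e-05, or adjusted p = 0.152 with an estimated correlation). Examples were Nr4a1 (4.91 ± 0.75, or 6.19 without vehicle library 3), Jun (3.74 ± 0.36), Ier3 (2.88 ± 0.65) and Fos (2.04 ± 0.35). Of 25 unfolded protein response genes 4 rose and 5 fell, or 4 and 8 adjusted over the list alone (median -0.74, camera adjusted p = 0.431), while lists matched on span and abundance had a median of 0.44 and a central 95% of 0.0091 to 0.84. With library totals alone 3 rose and 12 fell. Without vehicle library 1 the numbers were 2 and 2, without vehicle library 3 they were 4 and 2, without cisplatin library 1 they were 4 and 8, and without cisplatin library 3 they were 4 and 3. Those that rose included Ppp1r15a (2.87 ± 0.31), Ddit3 (2.45 ± 0.31) and Atf3 (3.06 ± 0.86), which act in the integrated stress response, and the chaperone gene Hsp90b1 changed by -1.34 ± 0.28. Atf3 was not called without cisplatin library 2 (adjusted p = 0.0510) or vehicle library 1 (adjusted p = 0.0992) and was at 4.42 without vehicle library 3.

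Oxidative stress and metallothionein genes were called as a list, with 4 of 16 higher and 0 lower, the same adjusted over the list alone (median 0.35, camera adjusted p = 0.00643, or adjusted p = 0.201 with an estimated correlation). The metal-binding Mt2 rose by 2.63 ± 0.30 and Mt1 by 1.24 ± 0.35, with Hmox1 at 1.85 ± 0.38 and Sod1 at 1.80 ± 0.29, and Mt1 was not called without vehicle library 1 (adjusted p = 0.109) or 2 (adjusted p = 0.0763). The list's median was -0.11 with library totals alone, still above the median of all rows. Ribosomal protein genes were called with 9 of 42 higher and 0 lower, the same adjusted over the list alone (median 0.56, camera adjusted p = 3.0e-04, or adjusted p = 0.243 with an estimated correlation). The number that rose was 1 of 43 without vehicle library 1, 4 of 43 without vehicle library 3 and 3 with library totals alone. Rplp1 rose by 1.98 ± 0.48, Rpl13 by 1.74 ± 0.32, Rplp0 by 1.45 ± 0.32 and Rpl18 by 1.30 ± 0.31, and Rplp1, Rplp0 and Rpl18 were not called without vehicle library 1 (adjusted p = 0.0525 to 0.0662). Lists matched on span and abundance had a median of 0.36 beside the oxidative stress list and 0.80 beside the ribosomal list.

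Metabolic lists were not called. Of 29 oxidative phosphorylation genes 6 rose, or 5 adjusted over the list alone (camera adjusted p = 0.0978), among them Cox6a1 (1.87 ± 0.32), Uqcrfs1 (1.56 ± 0.48), Cox4i1 (1.21 ± 0.32) and Sdha (1.07 ± 0.32). With library totals alone 1 rose and 3 fell and the list's median of 0.29 became -0.13, and 1 rose without vehicle library 1 or without vehicle library 3, where Uqcrfs1, Cox4i1 and Sdha were not called. Uqcrfs1 was also not called without cisplatin library 1 or 2 (adjusted p = 0.0521 and 0.0708) and was at 2.3 without vehicle library 2, and Sdha was not called without cisplatin library 3 (adjusted p = 0.0756) or vehicle library 2 (adjusted p = 0.0776). Of 15 pyruvate dehydrogenase and citric acid cycle genes 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.23). Pcx, the pyruvate carboxylase, changed by -3.98 ± 0.63, Suclg2 by -3.06 ± 0.60 and Idh3g by -1.48 ± 0.32, with a less abundant Idh3g probe not called at 0.27 ± 0.38, while Mdh2 rose by 1.64 ± 0.45. Pcx was at -3.37 without cisplatin library 1 and -5.33 without cisplatin library 3. The number that rose was 0 without vehicle library 1 or 3 or with library totals alone, and 1 with a mouse block or without cisplatin library 1 or vehicle library 2. Of 10 glycolysis genes 3 rose, also adjusted over the list alone, Tpi1 (1.76 ± 0.28), Pgam1 (1.5 ± 0.28) and Gpi1 (1.21 ± 0.27; camera adjusted p = 0.0577), and with library totals alone 2 rose and 1 fell. Of 9 platinum transport and detoxification genes 1 rose and 2 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.661). The copper chaperone gene Atox1 rose by 1.37 ± 0.46, and the exporters Abcc1 and Atp7a changed by -1.63 ± 0.48 and -0.98 ± 0.26. The numbers that rose and fell were 0 and 0 without cisplatin library 1, vehicle library 1 or vehicle library 3. They were 0 and 2 without cisplatin library 2, 2 and 1 without vehicle library 2, 2 and 2 with a mouse block and 0 and 3 with library totals alone. Abcc1 was called in the absence of a single library only for cisplatin library 3, at -2.29, and Atox1 only for vehicle library 2. The platinum list's median was -0.22 while its mean was 0.05 and its camera direction was up.

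**Figure D3:**
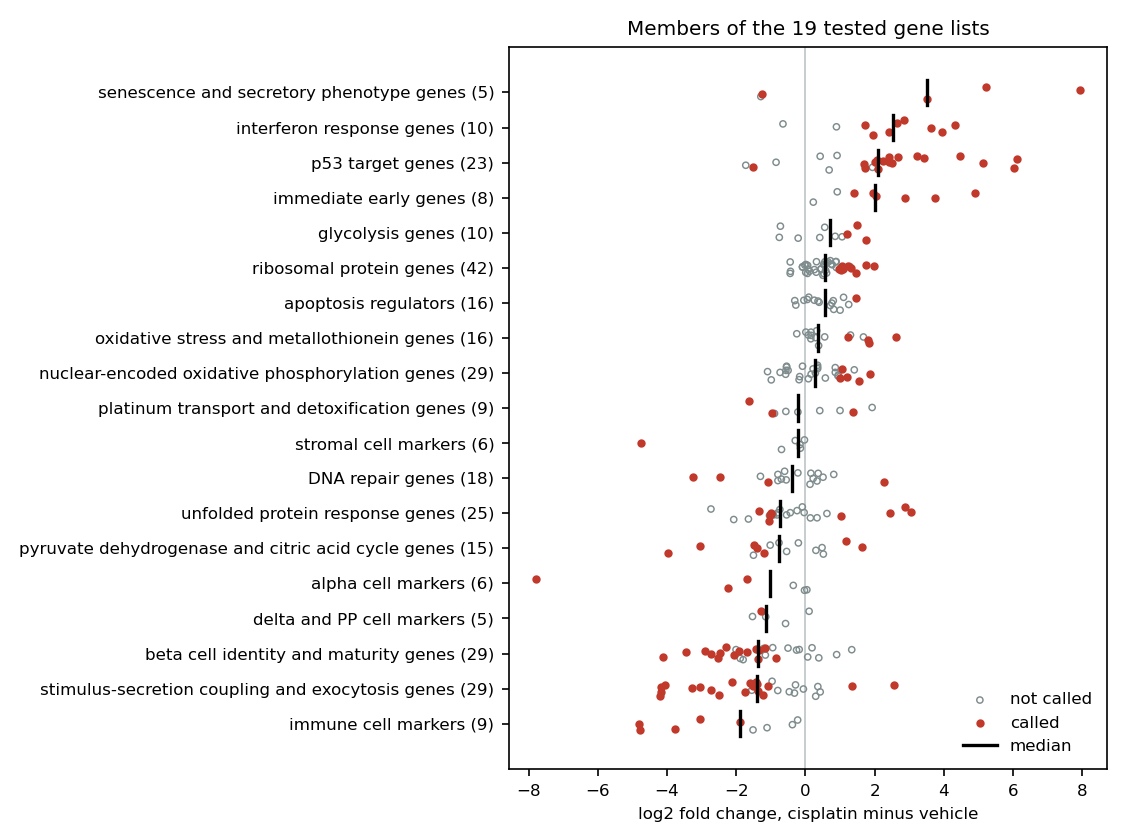
Log2 fold changes of the members of the 19 tested gene lists, cisplatin minus vehicle, with filled points called, open points not called, a black bar at the median and the number of tested members in brackets. The p53 target list has its median at 2.09 and the beta cell identity list at -1.36.

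The largest rises outside those lists were in Ifit1bl1, with 183 counts against 3 and a ratio of 128 (95% counting interval 43.2 to 627) and 2 of the 3 in vehicle library 2, in a probe of the mitochondrially encoded mt-Nd3 (5.66 ± 0.75), and in the little-described loci Gm4076 (5.18 ± 0.72) and A630095N17Rik (5.01 ± 0.51). Without cisplatin library 3 the mt-Nd3 probe was at 4.41 and Gm4076 at 3.98, and the more abundant mt-Nd3 probe rose by 4.28 ± 0.77. Mitochondrially encoded rows took 2.83%, 3.11% and 28.6% of the cisplatin libraries, and 1.74%, 0.188% and 0.770% of the vehicle libraries, and nearly all of these counts were of mt-Nd6 (96.0% to 99.6% in each library). The largest falls reported here were in probes of long genes, with spans of 79.7 to 2245 kb against a median of 24.1 kb for tested genes. A probe of Ppp1r13b, which codes for a p53 cofactor, had 0 counts with cisplatin and 177 with vehicle, at least 28.1-fold lower, while a more abundant probe of the gene was not called (-0.84 ± 0.43, adjusted p = 0.170). Adarb1, an RNA-editing enzyme gene, had 0 and 137 counts, at least 21.7-fold lower. The ratios of vehicle to cisplatin were 120 (21.4 to 4776) for the polarity gene Pard3b, 84.3 (14.9 to 3347) for a probe of App, the amyloid precursor gene, and 78.8 (21.6 to 653) for the adhesion gene Cntnap2 (chromosome 6, 45059357 to 47304213). The cisplatin count of Pard3b and of that App probe, 1 each, lay in cisplatin library 2. The more abundant App probe changed by -3.47 ± 0.48 and a less abundant Cntnap2 probe by -4.62 ± 0.67. A Jakmip1 probe changed by -6.47 ± 0.72, or -5.75 without cisplatin library 1 and -7.78 without cisplatin library 2, and the more abundant probes of that gene by -3.17 ± 0.44 and -2.64 ± 0.46. Among genes named by their most abundant probe, Phlda3 had a less abundant probe at 4.47 ± 0.52, and at least 1 less abundant tested probe was not called for Usp18, Fos, Atm, Vegfa, Hsp90b1, Hmox1, Sod1, Rplp0, Sdha, Gpi1 and Abcc1.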

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

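The row counts, called named genes and gene lists were recomputed under the alternatives named in the processing summary. Leaving out mitochondrial and repeat-like rows, the mitochondrial and repeat-like shares, and the combination of an estimated correlation with the mouse block were chosen after seeing the data. The called rows numbered 2197 to 2717 over the other scalings, filters and tests run on probe rows in all libraries, and 2100 with probes summed per gene. With library totals alone 459 rows were called higher and 2023 lower, since that scale moved the median of all rows to -0.54. An adjusted p under 0.01 left 1185 rows, 519 higher and 666 lower. Leaving out libraries or mice gave 1021 to 2538 rows, 424 to 1244 higher and 581 to 1294 lower. The lowest single-library count was 1085, without vehicle library 1, and 1321 rows were called without vehicle library 3. Without mouse 1, 2 or 3 and with no block the counts were 1350, 1511 and 1021. Without mouse 3 and with the mouse block 1107 rows were called, 443 higher and 664 lower. Such fits use fewer samples. Depth limits the shallow cisplatin libraries, yet thinning all libraries to one total still called 2263 rows.

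None of the 80 called named rows reported here reversed direction in any setting that gave a value. Library totals alone ended 12 of their calls (Atox1, Bcl2l11, Cox4i1, Esam, Gpi1, Mcm2, Mdh2, Mt1, Pcna, Rpl18, Sdha and Uqcrfs1), no filter those of Atox1, Esam and Pcna, thinning or DESeq2 with the block those of Esam and Pcna, limma-voom those of Atr and Eng, and summed probes that of Cacnb2, and leaving out libraries or mice ended 6 to 24. Of the 80, 25 lost their call without at least 1 single library, and 28 moved by over 1.5 times in fold. The mouse block called 2197 rows and ended the calls of Atr, Pcna and Esam. It changed no other call of a row named by the rule, and no list call at the preset correlation. Among named rows that were not called, Krt7 was -0.31 with library totals alone, -0.026 without mouse 3 under the block, and -0.14 to 0.49 without libraries or mice. Lmo4 was -0.072 and Ins2 -0.041 with library totals alone, and left-out ranges were -0.12 to 0.82 and -0.048 to 0.71. Gdf15 ranged from -0.63 (without mouse 1 under the block) to 1.11 and Ins1 from -0.77 to 0.18, with 0.15 without mouse 3 under the block. The cause of these sign changes was not tested, and each lies within 2 SE of 0 in the reported fit.

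With an estimated correlation 7 of the 8 list calls were lost. Adjusted p-values were 0.0517 for the beta cell identity and interferon lists, 0.120 for secretion, 0.152 for the immune and immediate early lists, 0.201 for oxidative stress and 0.243 for ribosomal genes. The estimates were -0.00482 for the beta cell identity list and -0.0884 for the interferon list, below the preset 0.01. Correlation within these lists is therefore not what raised their p-values. The other lost lists had estimates of 0.0235 (secretion), 0.0711 (oxidative stress), 0.0871 (immune), 0.119 (ribosomal) and 0.215 (immediate early). Under the block with an estimated correlation all 8 were lost, at 0.254 for the p53, beta cell and interferon lists, 0.311 for the secretion, immune, oxidative stress and immediate early lists and 0.445 for ribosomal genes. A fit of 6 libraries leaves few residual degrees of freedom for that estimate. The simulated list raised 2-fold, with rows drawn independently, had a camera adjusted p of 2.3e-11 at the preset correlation. With an estimated correlation it was 0.0265, so the estimated setting raised p there without correlation between rows. How much of the rise in the other lost lists came from correlation was not tested. Fry, which does not compare a list with other genes, called DNA repair (0.0350), apoptosis (0.0346), alpha cell (0.00783), citric acid cycle (0.0210), glycolysis (0.00133) and senescence genes (0.00429) as well. The senescence list was also called with library totals alone (0.00733), summed probes (0.0492), without the 10 most abundant rows (0.0235) and without mitochondrial and repeat-like rows (0.0220). The uncalled DNA repair list turned up with a filter at a mean CPM of 10 (0.964) and without cisplatin library 2 (0.956). The uncalled stromal list turned up with summed probes (0.928), without mitochondrial and repeat-like rows (0.846) and without cisplatin library 3 (0.855), vehicle library 1 (0.962) or vehicle library 3 (0.215). The uncalled platinum list turned down with the CPM filter (0.879) and with all probes (0.845). Without single libraries adjusted p ranged from 0.621 to 0.956 for DNA repair, 0.0405 to 0.228 for apoptosis, 0.0360 to 0.151 for alpha cell, 0.215 to 0.962 for stromal, 0.0127 to 0.279 for oxidative phosphorylation, 0.0406 to 0.0734 for glycolysis and 0.00330 to 0.0432 for senescence genes. No list call was lost without a single library. The cause of the changed list calls and directions was not tested further. The repeat-like share differed by 12.8 percentage points, and by 23.0 points once the 10 most abundant rows left the denominator, 2 of which are repeat-like themselves.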

Other observations

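Several abundant genes outside the fixed lists also changed, and they were picked after their values were seen. Nfkbia, which codes for an inhibitor of NF-kappaB, rose on both of its probes (2.26 ± 0.28 and 2.97 ± 0.32), and Cebpd, an acute-phase transcription factor, rose 11.6-fold. The epithelial genes Elf3 (3.28 ± 0.31), Krt8 (1.79 ± 0.26), Krt18 (1.73 ± 0.28) and Cldn4 (2.29 ± 0.38) rose, as did the heat shock gene Hspa1b (2.84 ± 0.33) and Ifi30 (2.66 ± 0.28). Both probes of Prkca, a protein kinase C gene, fell (-4.80 ± 0.47 and -4.52 ± 0.31), as did Atp2a2 (-3.34 ± 0.36) and Atp2a3 (-1.96 ± 0.32), the calcium pumps of the endoplasmic reticulum. Rapgef4, a cAMP sensor that acts in insulin secretion, fell by 3.78 on the log2 scale and Acly, the citrate lyase of lipid synthesis, by 2.18. Among the p53 targets the called member that fell was Cyfip2 (-1.51 ± 0.32), and among secretion genes those that rose were Vgf (2.57 ± 0.41) and Vamp2 (1.34 ± 0.28).

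Except for the comparison of the beta cell and secretion lists with span-matched lists, the tests below were written down after the values they measure had been seen. Of the 10 splits of the 6 libraries into 3 and 3, the real one called 2344 rows with edgeR and the highest other called 0, with 32 to 418 rows at an unadjusted p under 0.05, so 1 split reached that count. For lists, the real split called 8 and the highest other also called 8, so 3 of the 10 splits reached that number. With 10 splits no share under 0.05 is possible. Each other split puts cisplatin and vehicle libraries into the same group, which widens the spread within groups. Few called rows were thus likely in advance for those splits, and their 0 does not measure calls without a treatment difference. Of the 4 splits that part all 3 mouse pairs, the 3 others called 0 rows, and 2 of them called 8 lists.

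Genes that span more of the genome were lower with cisplatin. Over 7108 genes, each by its most abundant probe, span and log2 fold change had a Spearman rho of -0.561, across genes that are not independent replicates. The median log2 fold change was 0.72 for 839 genes of up to 5 kb, of which 247 were called higher and 16 lower, and -3.08 for 96 genes above 400 kb, of which 0 were called higher and 75 lower. A difference in depth is argued against by a rho of -0.578 among 1369 genes at 100 CPM or more after thinning, and transcript length, GC content and abundance by a partial rho of -0.475. The trend was in each mouse pair, with a rho of -0.462 or stronger, and rho was at most 0.0894 in size between libraries of 1 group, but this restates the pattern: lesions in long genes, RNA stability and probe position were not tested as its cause and stay open.

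Mitochondrially encoded rows and 4 predicted genes with shared repeated sequence (Gm10717, Gm10720, Gm17535 and Gm21738) took more of the cisplatin libraries. The mitochondrial share was 11.5% ± 14.8 against 0.900% ± 0.785 and the repeat-like share 16.2% ± 12.8 against 3.41% ± 1.5 (SD, n = 3, exact permutation p = 0.1 for both, the smallest possible), with cisplatin library 3 at 28.6% mitochondrial and cisplatin library 2 at 30.7% repeat-like. Without these rows 98.4% of called rows were called again, so on the TMM scale their counts did not decide most calls. TMM factors trim extreme rows, so a high share was likely in advance and does not speak for other scales. With library totals alone, which trim nothing, 459 rows were called higher and 2023 lower. One common background source as the whole cause is argued against by the ratio of mitochondrial to repeat-like counts, which differed 49.0-fold between libraries, although ratios within the mitochondrial rows also differed, 1.98-fold between the mt-Nd6 probes and 9.42-fold between other rows and mt-Nd6. An effect of cisplatin on these rows cannot be told apart from a difference in RNA quality between the arms, which was not tested: 16 of 16 tested rows were called higher (14 with a mouse block, 9 without vehicle library 1, 10 without vehicle library 3 and 6 without mouse 3), which restates the pattern.

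The beta cell identity and secretion lists fell (camera adjusted p = 0.0517 and 0.120 with an estimated correlation, and 0.254 and 0.311 with a mouse block as well), with median genomic spans of 16.8 and 47.3 kb against 24.1 kb for tested genes. Genomic span of the listed genes as the whole cause is argued against, since their medians of -1.36 and -1.40 lay at percentile 0 of 10000 lists matched on span and abundance, whose central 95% ran from -0.19 to 0.68 and from -0.76 to 0.22. A lower share of beta cells alone would raise markers of other cell types, yet 12 of 34 such markers were called lower and 1 higher. Of all 9381 tested rows 1304 were called lower and 1040 higher. The falls were uneven, in 5 of 9 immune, 3 of 6 alpha cell and 0 of 4 duct markers. Loss of several cell types together, lower transcription within cells and faster RNA decay were not tested and stay open.

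By the same matching the medians of the unfolded protein response and immune lists also lay at percentile 0, those of the delta and PP, alpha and citric acid cycle lists at percentiles 0.04, 0.11 and 0.96, and those of the p53, interferon, senescence and immediate early lists at 99.9 or higher. Those of the remaining 8 lists lay at percentiles 7.38 to 95.5, among them the ribosomal (7.38) and oxidative stress lists (49.4).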
